A study of Caenorhabditis elegans with 2 samples.

How the data were processed

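Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out against AMA-1, the largest subunit of RNA polymerase II, in whole L3 larvae of the Caenorhabditis elegans reference strain N2. L3 is a larval stage in which the somatic tissues are largely formed and the germ line is still growing. The labels describe 2 biological replicates of 1 group, animals of both sexes, and a fragment size range of 150 to 350 bp for each library. There was no second condition, so no test between groups of samples was possible. The labels point to a control experiment, whose libraries were not analysed here.

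The authors deposited 8 peak lists in narrowPeak format with 10 columns, in builds ce10 and ce11. Peaks had been called by the authors per replicate and on the pooled reads of both replicates, each as a permissive list of 30000 regions that served as input for the irreproducible discovery rate (IDR), a measure of how repeatably a peak ranks in replicates. Another list per build holds the authors' optimal IDR-thresholded peaks, called the optimal peaks below. Column 7 of the deposited lists holds a signal value per peak, which is the authors' own value on a scale that the sources used here do not give, and it was used only within a list, to describe, rank, filter, match or compare peaks. Column 9 of the deposited lists holds a −log10 q value per peak, which was only described. The column for p-values holds -1 in every line and was not used. The aligner, the peak caller, the IDR threshold, the read length and the sequencing depth are not given in the sources used here. The depth per library is therefore unknown, and a gene without a peak is one at which no optimal peak was found, not one without polymerase.

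The ce11 lists were the main data, because ce11 is the same assembly as the WBcel235 reference, and no region of the 8 lists reached past the end of a WBcel235 chromosome. Gene positions and classes came from the Ensembl annotation of WBcel235. A protein-coding gene was counted as promoter-occupied when the summit of at least 1 optimal peak lay within 500 bp of its annotated 5′ end, on either side, and 1 summit could count for several genes. Distances from gene ends are in gene direction, so that negative values lie upstream. In this species many transcripts lose their first part by trans-splicing, and the annotated 5′ end is then often the splice site and not the start of transcription.

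Fixed before the data were examined were the promoter window, the tests, the gene lists, the rule for named genes and most of the alternatives. The 33 gene lists were written from gene names and families. Each was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 33 lists at 0.05. Because neighbouring genes share peaks, genes are not independent replicates, and each list was tested again against 1000 circular shifts of the peaks along each chromosome by at least 20000 bp. Replicate overlap was the share of the 3052 strongest peaks of a replicate with a summit of the other replicate's 3052 strongest within 200 bp, 3052 being the number of optimal peaks, tested one-sided against 1000 shifts. Rank agreement was Spearman's rho across the optimal peaks found in both replicate lists, with 100000 resamples. X-linked and autosomal genes, and genes in the middle and outer parts of the autosomes, were compared by Fisher's exact test. The positions of summits and the 10 classes of noncoding genes were tested against 1000 shifts, two-sided, with Benjamini-Hochberg adjustment over the classes. The median signal of a list's occupied genes was set against 10000 random lists of the same size. The smallest p these shifts can give is 0.001 one-sided and 0.002 two-sided.

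The genes named are, by that rule, the 20 protein-coding genes with the strongest promoter peak (1 gene per peak), the 2 members with the strongest peak of each gene list described and the first 2 members without one (every member where 5 or fewer had or lacked a peak), the 5 noncoding genes other than piRNA genes with the strongest peak, and ama-1. Not every gene that the rule takes is printed. Genes named outside it were chosen after their values were seen. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and a count of 0 carries the share that 3 counts would give.

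The alternatives changed 1 choice at a time: windows of 250 and 1000 bp, any overlap of a peak with the window, each summit counted for its nearest 5′ end only, no genes likely to lie inside operons, the 1526 strongest optimal peaks, the 6104 strongest pooled regions, the gene body added to the window, and each replicate alone with its 3052 strongest peaks. Added after seeing the data were a window at the 3′ end, the body with the 3′ flank, summits nearer a 5′ than a 3′ end, genes without repeated promoter sequence, genes that share no promoter window, shifted peaks at the 3′ end and in the gene body, each replicate alone in these windows, and the rank agreement over all 30000 pooled regions. Sequence was called repeated where its 31-mers occur more than once in the reference, and a promoter window was called unique when under 10% of its 31-mers were repeated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

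The list test was tested on simulated data with 19973 genes and 20 simulations, in which 5 lists were given an occupied share of 30% against 6% elsewhere. The planted lists were the ribosomal proteins, proteasome, histones, neurons and cell cycle above, and the chemoreceptors below. The test recovered 99% of the lists planted above and the list planted below in 100% of simulations, and called 1.30% of the other lists. No list with fewer genes than the 33 of the proteasome was planted, and genes were drawn independently. These rates may therefore differ for smaller lists and for neighbouring genes occupied together. With no list planted, 0.758% of lists were called. The shift test called 0 of 10 peak sets placed at random and 10 of 10 sets in which part of the peaks was placed at 5′ ends.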

Results

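AMA-1 ChIP-seq of N2 L3 larvae was analysed as 2 biological replicates of 1 group, so the results below describe where the polymerase was found in this stage and how far both replicates gave the same picture. The optimal list held 3052 peaks in ce11, with widths from 80 to 3409 bp and a median of 320 bp. These peaks covered 957 kb, or 0.955% of the 6 chromosomes, and all of them were the 3052 strongest of the 30000 regions called on the pooled reads. The remaining 26948 pooled regions were not in the optimal list. Membership thus followed the pooled signal, and does not show that a single peak was repeatable. Within 200 bp, 3026 optimal peaks had a region in the permissive list of replicate 1 and 2831 in that of replicate 2. The signal of the optimal peaks ran from 57.9 to 1168 with a median of 79.2. Their GC content averaged 41.2% ± 5.72 (SD across peaks) against 35.3% ± 6.39 in 6000 random windows, and 0.229% of the peaks were mostly repeated sequence against 7.12% of those windows.

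How far the replicates marked the same positions was asked first. The 3 strongest pooled peaks all lay at genes for SL2 RNAs, the small RNAs that donate the spliced leader to downstream genes of operons, and the strongest of all, at sls-2.4 on chromosome I, ranked 1 in replicate 1 and 2 in replicate 2. The peak at mdt-26, which encodes a subunit of the Mediator complex, ranked 8 and 7, and that at tos-1 ranked 13 and 10. Other strong peaks ranked far apart, such as the peak by C47E8.11 and the 3′ end of hsp-90, at rank 23 in replicate 1 and 14468 in replicate 2. Of the 3052 strongest peaks of replicate 1, 46.6% had a summit within 200 bp among the 3052 strongest of replicate 2, and 47.6% in the reverse direction. Circularly shifted peaks gave a mean of 1.23% and at most 2.03% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the optimal peaks, 2806 (91.9%) had a matching region in both permissive lists, and across these the ranks of the signal correlated weakly, with Spearman's rho = 0.18 (permutation p = 1e-05, the smallest possible). Across 15081 matched regions of the whole pooled list rho was 0.44, a setting chosen after the data were seen. Peaks are not independent replicates, and the optimal list spans only the strong end of the range.

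**Figure D1:**
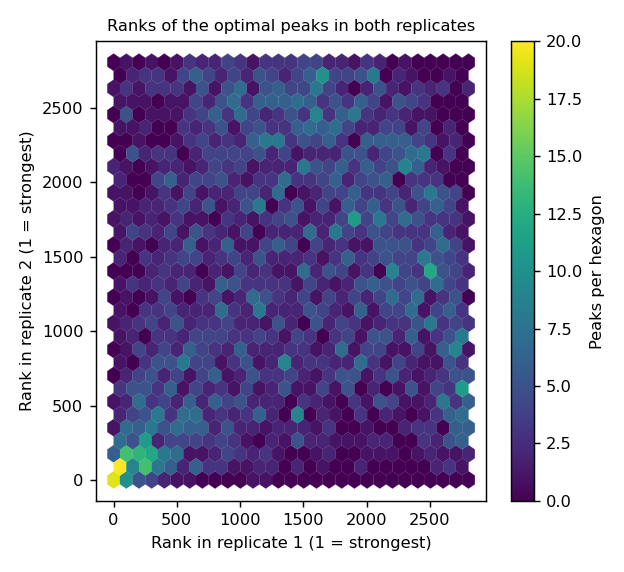
Rank of each optimal peak's signal in replicate 1 (x axis) and replicate 2 (y axis), 1 being the strongest, for the 2806 peaks found in both replicates, with colour giving the number of peaks per hexagon. Peaks gather in the corner of the strongest ranks and spread widely elsewhere, with Spearman's rho = 0.18.

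At the protein-coding genes, the strongest promoter peak by the signal on the pooled reads, which orders all peaks named below, was that of mdt-26 (WBGene00016115, chromosome II, 5661181 to 5665243), whose summit at 5661246 lay in an exon 65 bp inside the 5′ end, with a signal of 823. It was followed by tos-1 (WBGene00019466, chromosome V), with an exonic summit at 9344165 and a signal of 677, and by ego-1, an RNA-dependent RNA polymerase gene of the germ line, with a summit at 7656747 on chromosome I and a signal of 554. The ego-1 peak ranked 9 in replicate 1 and 893 in replicate 2, so its place rests on replicate 1. Among the other genes with the strongest peaks were dpy-11, which encodes a thioredoxin-like protein needed for body shape (signal 440), wwp-1, a ubiquitin ligase gene (388), cpz-1, a cathepsin gene (355), osm-11, which encodes a Notch co-ligand (352), lgg-1, the autophagy gene of the Atg8 family (327), and pcf-11, which encodes a factor of transcript 3′ end processing (307). In 5 of the 20 genes with the strongest promoter peaks the summit lay nearer to another gene's 3′ end than to their own 5′ end. These were ego-1, 231 bp past the 3′ end of F26A3.4, ufbp-1 (ranks 16 and 2215 in replicates 1 and 2), past that of the chaperone gene hsp-110, fbxb-72, 147 bp past that of icl-1, nlp-76, 185 bp past that of nhr-17, and kel-3, inside cdk-5. The kel-3 summit, at 13464720 on chromosome III, also lay past the 3′ end of ant-1.1, at 13464652. The gene of the immunoprecipitated protein itself, ama-1 (WBGene00000123, chromosome IV, 4248070 to 4258169), had no promoter peak in the optimal list.

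Promoter-occupied were 1213 of 19973 protein-coding genes (6.07%, 95% interval 5.75 to 6.41%), against a mean of 551 genes (2.76%) with shifted peaks. Which groups of genes these were was tested with 33 lists, of which 10 lay above the other genes, 3 below, and 20 did not pass. The genes of protein synthesis held the highest shares. Of the ribosomal protein genes, 49 of 80 were occupied (61.3%, 49.7 to 71.9%, 10.5 times the share of other genes, Fisher's exact adjusted p = 7.4e-38). Examples are rps-12 (chromosome III, summit 5679116, signal 206) and rpl-3 (chromosome III, summit 3867554, signal 194), while rla-0 and rla-2 had no promoter peak. Of the translation elongation factor genes, 5 of 6 were occupied (83.3%, adjusted p = 2.2e-05 by Fisher's exact test), namely eef-1B.1, eef-1A.1, eef-2, eef-1A.2 and eef-1G, and eef-1B.2 was not. Summits of the occupied ribosomal protein genes stood at a median of -300 bp from the annotated 5′ end, with 39 of the 49 further than 250 bp upstream, against a median of -107 bp over all occupied genes. The share of ribosomal protein genes was therefore 9 of 80 (11.3%, Fisher's exact adjusted p = 0.0212) with a window of 250 bp, and it was 35.0% when each summit counted only for its nearest 5′ end. Without genes that share a promoter window, 2 elongation factor genes were left and that list no longer passed (Fisher's exact adjusted p = 0.207).

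Genes of energy metabolism and protein quality control were also occupied more often than other genes. The vacuolar ATPase, the proton pump of lysosomes and other membranes, had 10 of 21 genes occupied (47.6%, 25.7 to 70.2%, Fisher's exact adjusted p = 6.9e-07), among them vha-2 and vha-1 with signals of 107 and 106. Heat shock and chaperone genes had 26 of 67 (38.8%, 27.1 to 51.5%, Fisher's exact adjusted p = 4.8e-14). Their strongest promoter peak, with a signal of 212, lay in an exon of the small heat shock gene hsp-16.2 on chromosome V (summit 1804854), 103 bp inside its 5′ end, and counted also for the divergent neighbour hsp-16.41. It ranked 70 in replicate 1 and 2132 in replicate 2. The genes cct-2 and cct-3 had none. Oxidative phosphorylation had 17 of 53 genes occupied (32.1%, 19.9 to 46.3%, exact adjusted p = 6.2e-08), led by cox-5B (signal 189) and the adenine nucleotide carrier gene ant-1.1 (183). The proteasome had 10 of 33 (30.3%, 15.6 to 48.7%, exact adjusted p = 6.9e-05), led by rpn-3 (180). These 4 lists, the ribosomal proteins and the elongation factors were the 6 above the other genes in the shift test as well, with adjusted p of 0.033 for the proteasome and 0.011 for the others. The proteasome list did not pass with the 1526 strongest peaks alone (3 of 33 genes, exact adjusted p = 0.227), and without replicate 1 it had 6 of 33 (18.2%, exact adjusted p = 0.0376).

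In 4 further lists the share was above that of other genes by Fisher's exact test but not by shifted peaks. Glycolysis had 5 of 17 genes occupied (29.4%, exact adjusted p = 0.00822, 0.119 by shifts), namely gpd-3, gpd-2, aldo-2, pyk-1 and gpi-1. The summit counted for gpd-2 lay 191 bp from its 5′ end but only 170 bp past the 3′ end of mai-1. That of gpd-3 lay 195 bp from its own 5′ end and 297 bp past the 3′ end of gpd-2. Tubulins and actins had 6 of 21 (28.6%, exact adjusted p = 0.00402, 0.186 by shifts), led by act-4 (signal 219) and tba-2 (138). Splicing factors had 8 of 48 (16.7%, exact adjusted p = 0.0198, 0.345 by shifts), led by hrpu-1 and rsp-6. Cuticle collagens, the structural proteins of the body covering that is renewed at each moult, had 20 of 176 (11.4%, exact adjusted p = 0.0175, 0.209 by shifts), with the highest pooled signals at dpy-13 (179, ranks 139 and 2974 in replicates 1 and 2) and col-103 (146, ranks 816 and 142). Glycolysis and the tubulins and actins also missed the threshold with a window of 250 bp (exact adjusted p = 0.311 and 0.407), the tubulins and actins also without replicate 1 (4 of 21, 0.0879), the splicing factors without likely operon genes (0.0893), and the collagens with either replicate alone (0.0879 and 0.0714).

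**Figure D2:**
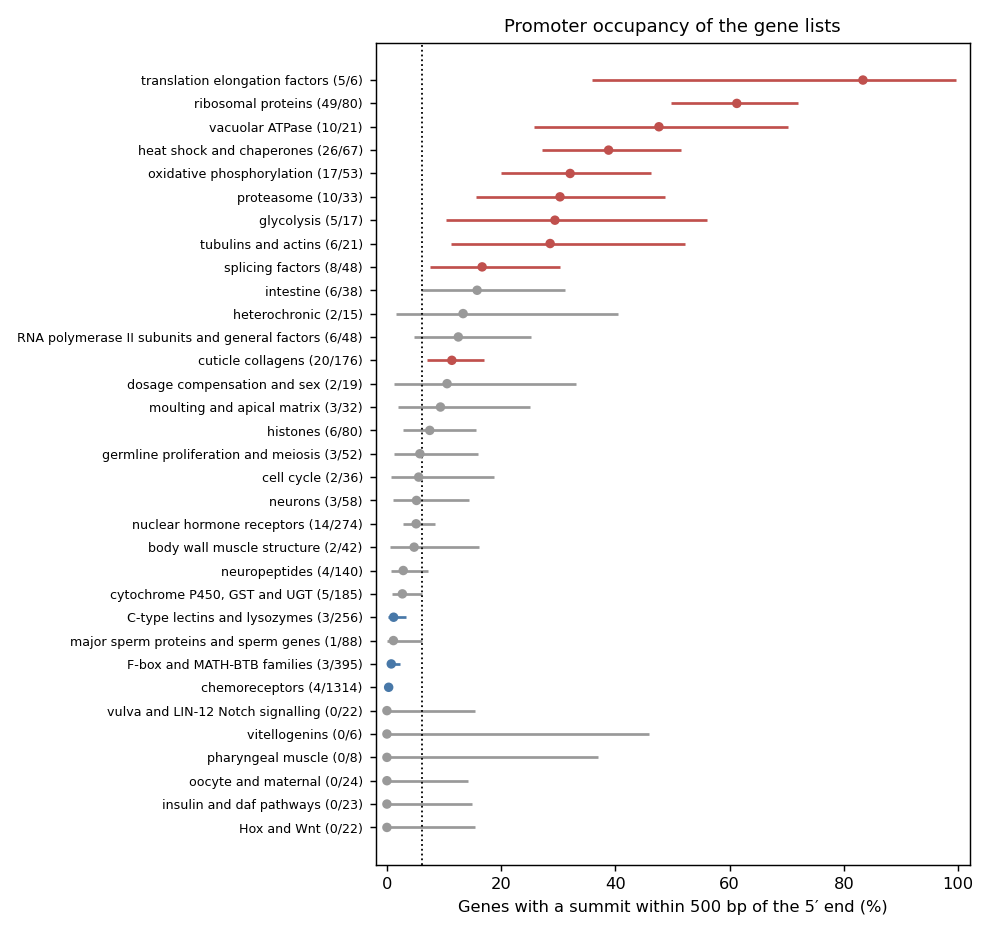
Share of each gene list with an AMA-1 summit within 500 bp of the 5′ end (x axis, percent) for the 33 lists (y axis, occupied over all genes in brackets), as points with exact 95% intervals; red lists lay above and blue lists below the other genes by Fisher's exact test after adjustment, grey lists did not pass, and the dotted line is the share of all protein-coding genes, 6.07%. The 49 of 80 ribosomal protein genes and 5 of 6 elongation factor genes stand furthest right, and chemoreceptors (4 of 1314) lie among the lists furthest left.

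The 3 lists below the other genes were large gene families. Chemoreceptor genes, expressed in sensory neurons, had 4 of 1314 occupied (0.304%, 0.0830 to 0.778%, Fisher's exact adjusted p = 7.9e-30), which were srh-269, srbc-58, srh-16 and sri-5. The summit counted for srh-269 lay 349 bp from its 5′ end but only 181 bp past the 3′ end of cpl-1. The F-box and MATH-BTB families, adaptors of ubiquitin ligases, had 3 of 395 (0.759%, 0.157 to 2.203%, Fisher's exact adjusted p = 6.2e-07), which were fbxb-72, fbxb-85 and bath-44. C-type lectins and lysozymes, many of them immune genes, had 3 of 256 (1.17%, 0.242 to 3.39%, Fisher's exact adjusted p = 0.000646), which were clec-1, clec-126 and clec-196. The summit counted for clec-196 lay 229 bp from its 5′ end but nearer to the 3′ end of lhfp-4, at -138 bp. It had no region within 200 bp in the permissive list of replicate 2. By shifted peaks the first pair of lists passed (permutation adjusted p = 0.011 and 0.033) and the lectins and lysozymes did not (0.119).

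Of the lists that did not pass, several marked tissues. Body wall muscle structure had 2 of 42 genes occupied (act-4 and unc-60), pharyngeal muscle 0 of 8 (which allows up to 37.5%), the intestine 6 of 38 (15.8%, adjusted p = 0.0608), neurons 3 of 58 (daf-19, egl-21 and ida-1), and neuropeptides 4 of 140 (nlp-76, nlp-33, nlp-24 and nlp-15; adjusted p = 0.277 by Fisher's exact test). The intestinal list passed with a window of 250 bp (exact adjusted p = 0.0462). Vitellogenins, the yolk proteins made by adults, had 0 of 6 (up to 50%), oocyte and maternal genes 0 of 24 (up to 12.5%), germline proliferation and meiosis 3 of 52 (brc-1, syp-4 and cgh-1), and sperm genes 1 of 88 (spe-5; adjusted p = 0.097 by Fisher's exact test). Repeated sequence limits the low counts of sperm genes and vitellogenins, since 53.4% and 50% of their promoters hold it; among unique promoters the sperm genes had 1 of 41 and the vitellogenins 0 of 3. Among regulators of development, Hox and Wnt genes had 0 of 22 and genes of the vulva and LIN-12 Notch signalling 0 of 22 (each up to 13.6%), insulin and daf pathways 0 of 23 (up to 13.04%), heterochronic genes 2 of 15 (ain-1 and nhr-85), dosage compensation and sex 2 of 19 (dpy-28 and dpy-21), nuclear hormone receptors 14 of 274 (5.11%), and moulting and apical matrix 3 of 32 (nhr-25, wrt-1 and noah-2). The wrt-1 peak had no region within 200 bp in the permissive list of replicate 2. RNA polymerase II subunits and general factors had 6 of 48 (12.5%, exact adjusted p = 0.134), led by taf-4 (signal 267), and passed at 250 bp (0.0383) and with the 6104 strongest pooled regions (0.000305). The cell cycle list had 2 of 36 (pcn-1 and mcm-7), and the detoxification list of cytochrome P450, GST and UGT genes 5 of 185 (2.70%, exact adjusted p = 0.126), all 5 of them gst genes, and that list lay below the other genes without replicate 1 (3 of 185, exact adjusted p = 0.0157). Histones had 6 of 80 (7.50%, exact adjusted p = 0.669), led by his-24 and the histone H3.3 gene his-72. Most histone promoters hold repeated sequence, and the list passed among the 17 genes with unique sequence, where the same 6 were occupied (35.3%, exact adjusted p = 0.00196), a subset chosen after the data were seen.

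Within the occupied genes, the strength of the peak separated no list from the rest. In the median signal, 0 of 22 lists with at least 3 occupied genes passed against 10000 random lists after adjustment. At an unadjusted p under 0.05 there were 3, namely histones (median 140.4, permutation p = 0.0174), heat shock and chaperones (99.8, p = 0.024) and neuropeptides (149, p = 0.0338), against a median of 80.5 over all occupied genes. By the signal of replicate 2 alone the heat shock list had a median of 29.4 against 27.4 (permutation p = 0.508), the histones 55.6 (p = 0.0058) and the neuropeptides 48.2 (p = 0.0656). By that of replicate 1 alone p was 0.0532, 0.0552 and 0.0486 in the same order.

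Occupied promoters were unevenly spread over the chromosomes. Chromosome III held the highest share, 261 of 2640 genes (9.89%, 8.77 to 11.1%), followed by I with 8.13%, IV with 6.13% and II with 5.62%. Chromosome V with 209 of 4994 genes (4.19%, 3.65 to 4.78%) and X with 114 of 2731 (4.17%, 3.46 to 4.99%) held the lowest. X-linked genes, most of which are silent in the germ line in this species, were occupied less often than autosomal genes (1099 of 17242, 6.37%), at 0.655 times their share (Fisher's exact p = 3.7e-06). In the central parts of the autosomes, 711 of 9597 genes were occupied (7.41%), against 388 of 7645 in the outer parts or arms (5.08%), a ratio of 1.46 (Fisher's exact p = 3.9e-10). Both tests take genes as independent, although neighbours can share a peak.

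**Figure D3:**
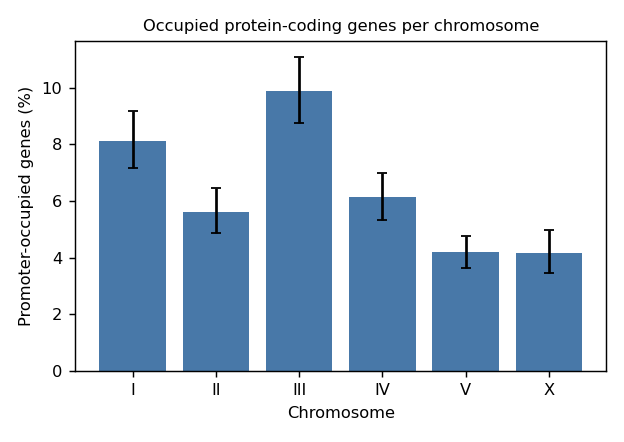
Share of protein-coding genes with a promoter peak (y axis, percent) on each of the 6 chromosomes (x axis), with exact 95% intervals as error bars. Chromosome III stands highest at 9.89%, and V (4.19%) and X (4.17%) lowest.

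Summits gathered at both ends of genes. Within 500 bp of a protein-coding 5′ end lay 1123 summits (36.8%, 35.1 to 38.5%), against a mean of 18.8% with shifted peaks (ratio 1.96). Within 500 bp of a 3′ end lay 1065 summits (34.9%, 33.2 to 36.6%), against 17.1% (ratio 2.04), and 601 of these (19.7% of all summits, against 12.1%) were at no 5′ end. With a window of 1000 bp, the share at 3′ ends alone no longer differed from that of shifted peaks (16.9% against 15.7%, permutation p = 0.104). Fewer summits than with shifted peaks lay elsewhere in exons (12.3% against 16.6%), in introns (16.5% against 27.7%) and between genes (14.7% against 24.9%). Each of these shares had, with the window of 500 bp, a permutation p = 0.002, the smallest that 1000 shifts can give. Around 5′ ends the fullest 50 bp bin was -200 to -150 bp, with 116 summits against 29.1 with shifted peaks. Past 3′ ends it was 150 to 200 bp downstream, with 174 summits against 29.2, while the last 50 bp of genes held 11. Of the summits at 5′ ends, 155 (13.8%) lay nearer to a 3′ end, so the share at promoters and that at 3′ ends overlap.

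**Figure D4:**
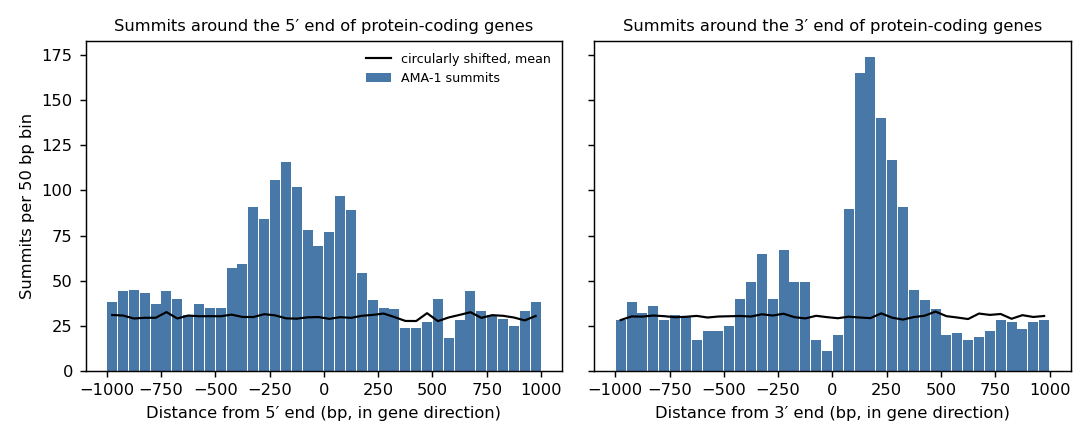
Number of optimal peak summits per 50 bp bin (y axis) by distance in gene direction from protein-coding 5′ ends (left, bp) and 3′ ends (right, bp), as bars, with the mean of shifted peaks as a line. Bars reach 116 upstream of 5′ ends and 174 at 150 to 200 bp past 3′ ends, where the line stays near 29.2.

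Noncoding genes gave the strongest peaks of all. The peak with the highest signal (chromosome I, 4172076 to 4172513, summit 4172297, signal 1168) lay inside the SL2 RNA gene sls-2.4 and the overlapping noncoding gene R12E2.18, the next (chromosome II, summit 5543598, signal 1035) at sls-2.2 and C17C3.23, and the third (chromosome II, summit 5844928, signal 991) at sls-2.1. Small nuclear RNA genes, the class that holds the SL2 genes, had a summit within 500 bp of the 5′ end in 30 of 129 cases (23.3%, 16.3 to 31.5%), against a mean of 2.69% with shifted peaks. Small nucleolar RNA genes, which guide the modification of ribosomal RNA, had one in 98 of 346 (28.3%, against 2.86%), and microRNA genes in 41 of 261 (15.7%, against 2.74%). Transfer RNA genes, transcribed by RNA polymerase III, had 44 of 612 (7.19%, against 2.57%), and genes annotated only as noncoding RNA 472 of 7764 (6.08%, against 2.63%). Below the shifted peaks were pseudogenes with 13 of 2128 (0.611%, against 2.65%) and piRNA genes, the germline small RNA genes, with 141 of 15363 (0.918%, against 2.45%). All 7 classes had an adjusted p of 0.00285, from the smallest p that 1000 shifts can give. Long intergenic RNA genes (9 of 194, 4.64%, permutation adjusted p = 0.29) and antisense RNA genes (3 of 100) did not pass, although the former did with a window of 1000 bp (10.3%, adjusted p = 0.0125). Ribosomal RNA genes had 0 of 20, which allows up to 15%, and 90% of their promoters hold repeated sequence. Many noncoding genes lie inside or beside other genes, and a peak near them was not assigned to 1 transcript; among snRNA genes over 1000 bp from any protein-coding 5′ end the share was 13.8%, and among those with a unique promoter it was 36.8%.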

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

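The tests in this part were chosen after the patterns had been seen, and only the predictions for nearness to gene ends (first pattern) and for noncoding genes (second pattern) were written before their results. The 26948 pooled regions outside the optimal list were left out of the main comparisons, and entered only through alternatives, with the 6104 strongest pooled regions and with all 30000 for the rank correlation. Of their summits, 24.1% lay within 500 bp of a protein-coding 5′ end, against 18.6% with shifted peaks (permutation p = 0.002, the smallest possible). Their summits also lay more often than shifted ones in exons away from gene ends (22.6% against 16.6%), while those of the optimal peaks lay there less often (12.3% against 16.6%). The design holds 1 group, so no biological difference between groups of samples was tested for the patterns below.

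The first pattern is a difference between replicates. Peaks of ribosomal protein genes ranked higher in replicate 2 than in replicate 1 at 41 of 53 peaks, with a median rank difference of 401. This was first noticed in the signal values themselves and then measured as ranks among the 2806 optimal peaks found in both replicates. The difference stood at the 99.98th percentile of random peak lists matched on signal and GC content (permutation adjusted p = 0.0168), which argues against GC content as the whole source. The adjustment covers the 28 lists but not the several matchings tried. The difference stood at the 99.78th when matched on signal alone (permutation adjusted p = 0.129). Matched on signal and nearness to gene ends it stood at the 99.35th (0.185), where random lists had a median of 73. Over all peaks the median difference was 85 at 5′ ends and 38.5 at 3′ ends alone. These medians, and that of the random lists, were below the 401. The percentiles make no allowance for a list singled out among 28, and neither of these matchings passed after adjustment. Peak strength, nearness to gene ends and chance therefore stay open. Oxidative phosphorylation genes moved the same way, with a median difference of 545 and 18 of 24 peaks higher in replicate 2. Theirs stood at the 99.48th percentile matched on signal, the 99.4th with GC content added and the 99.55th with gene ends added. None of these passed (permutation adjusted p = 0.148, 0.171 and 0.185). A difference between the 2 animal populations, in stage within L3 for example, and a difference in library preparation may each be the source of the ribosomal protein pattern. With 1 library per population neither was tested.

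The second pattern is the gathering of summits past the 3′ ends of protein-coding genes. In the 500 bp past 3′ ends a summit was found at 899 of 19973 genes (4.50%), 3.02 times the mean of shifted peaks. At 8125 genes whose 3′ end lies over 2000 bp from the 5′ end of any other protein-coding gene the ratio was 2.36, and at 6600 genes also far from annotated noncoding 5′ ends it was 1.96 (each permutation p = 0.002, the smallest possible), which argues against promoters of annotated neighbours as the whole source. The ratio was nevertheless higher, at 3.46, where another protein-coding 5′ end was near, so neighbours may add to it. Polymerase that slows or pauses after the cleavage site is a candidate explanation that these data do not test, and unannotated promoters stay open.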

How the results depend on the processing

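The window at the 3′ end, the body with the 3′ flank, summits nearer a 5′ end, unique promoters, unshared windows, shifted peaks at the 3′ end or in the gene body, each replicate alone in these windows and the 30000 pooled regions were chosen after seeing the data. Direction and side of the threshold were kept in all 15 alternatives by the X against the autosomes (ratios 0.589 to 0.793, largest p = 0.0156) and centres against arms (1.31 to 1.77), as well as in all alternatives run for replicate overlap (37.7 to 54.7%), rank agreement (rho 0.19 to 0.44), 5′ ends (ratio 1.504 to 2.57), all summits at 3′ ends (1.42 to 2.46), exons (0.688 to 0.894), introns (0.525 to 0.632) and intergenic summits (0.490 to 0.767). Summits at 3′ ends alone lost their call with 1000 bp (ratio 1.08, p = 0.104, permutation). With that window 1593 summits were counted first as at 5′ ends, against 1123 with 500 bp. Each 50 bp bin from 500 to 1000 bp past 3′ ends held fewer summits than with shifted peaks. How much each of these added to the loss was not tested. The count of lists above the other genes was 10 and changed to 6 with shifted peaks, a test that keeps neighbouring genes together and whose smallest adjusted p here was 0.011; it was 7 with the 1526 strongest peaks, 8 without likely operon genes, 12 with the body and 3′ flank, and 8 to 11 otherwise. The count of lists below was 3 and changed to 6 with the 6104 strongest pooled regions and to 5 with the gene body added, and was 2 to 4 otherwise; the cause was not tested. Over the 561 results of single lists, 516 kept their call, 26 lost it and 19 gained it, and of the 60 results of noncoding classes 59 kept their call and 1 gained it. Of 165 results of single lists in the gene body or at 3′ ends, 147 kept their call, 12 lost it and 6 gained it, and with shifted peaks 10 lists lay above and 4 below in the gene body. With 1 replicate left out, 8 to 9 lists lay above and 3 to 4 below (9 to 10 and 4 to 5 in the gene body, 9 to 10 and 3 to 4 at 3′ ends), X to autosome ratios were 0.589 to 0.792, centre to arm ratios 1.39 to 1.59, ratios at 5′ ends 1.83 to 1.96 and at 3′ ends 1.88 to 2.32 (3′ ends alone 1.54 to 1.75), of exons 0.779 to 0.891, introns 0.583 to 0.604 and intergenic summits 0.490 to 0.642, 5 noncoding classes lay above and 2 below, and 0 lists stood apart in signal. ce10 held 2981 optimal peaks and merging overlapping ones left 2960. A stricter IDR limit was not run, because the lists used here give no IDR value per peak. No paired analysis was possible because there was 1 group. Depth is unknown and limits what a missing peak can show.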

Other observations

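The tests in this part with the gene body were planned, while those of the gene body with shifted peaks or each replicate alone, those at 3′ ends, those of histone genes by repeated sequence and the count of spliced leader genes were chosen after seeing the data; genes named here were chosen after their values were seen. Heterochronic genes, which set the timing of larval stages, had a promoter peak in 2 of 15 cases (13.3%, not passing), and 8 of 15 (53.3%) had a summit anywhere from 500 bp upstream of the 5′ end to the 3′ end, against 8.67% of other genes (Fisher's exact adjusted p = 4.9e-05). The count was 7 of 15 without replicate 1 and 8 of 15 without replicate 2 (exact adjusted p = 0.000698 and 4e-05). Their strongest summits by pooled signal lay in introns of lin-14 (14674 bp from the 5′ end), lin-42 (7839 bp), daf-12 (2053 bp), dre-1 (8087 bp), nhr-23 (2541 bp) and nhr-85 (1588 bp, signal 162), and in exons of lin-29 and ain-1; most of these summits ranked higher in replicate 1, lin-14 for example at 605 against 5110 and daf-12 at 1813 against 19282. Several of these genes are long, which gives a summit more room; against shifted peaks, which leave each gene its length, the adjusted p was 0.0355 (permutation). Moulting and apical matrix genes had 8 of 32 (25%, Fisher's exact adjusted p = 0.012) by the same measure, against 3 of 32 at promoters, but only 4 of 32 without replicate 1 (12.5%, exact adjusted p = 0.71), and they did not pass against shifted peaks (permutation adjusted p = 0.132).

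In the same window the neuropeptides (4 of 140, exact adjusted p = 0.0215) and the detoxification genes (7 of 185, exact adjusted p = 0.0258) lay below the other genes, which at promoters they did not. Without replicate 2 neither passed (exact adjusted p = 0.195 and 0.0606), nor did they against shifted peaks (permutation adjusted p = 0.43 and 0.249). The insulin and daf pathways had 3 of 23, and 8 of 23 without replicate 1 (34.8%, exact adjusted p = 0.00225), while the sperm genes had 2 of 88, and 1 of 88 without replicate 2, then below the other genes (exact adjusted p = 0.0245). The collagens, with 20 of 176, no longer passed by the exact test (adjusted p = 0.353). The proteasome and the tubulins and actins, above the other genes here, no longer passed without replicate 1 (7 of 33 and 4 of 21, exact adjusted p = 0.0689 and 0.225), nor the splicing factors without replicate 2 (7 of 48, 0.189) or against shifted peaks (permutation adjusted p = 0.0659). Against shifted peaks the collagens passed above (permutation adjusted p = 0.0471) and body wall muscle structure, with 2 of 42, below (0.0355).

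The 10 lists above and the 3 below the other genes at promoters were so at 3′ ends as well by Fisher's exact test. The counts at both ends are not independent, since 464 of the 3052 summits lay within 500 bp of a 5′ end and of a 3′ end. A summit within 500 bp of the 3′ end was found at 25 of 67 heat shock and chaperone genes (37.3%, exact adjusted p = 2.6e-13), at 8 of 17 glycolysis genes (47.1%), at 26 of 176 cuticle collagens (14.8%) and at 17 of 80 ribosomal protein genes (21.3%), against 5.81% of all protein-coding genes. The vacuolar ATPase and the tubulins and actins had 7 of 21 each, the proteasome 11 of 33, oxidative phosphorylation 14 of 53, splicing factors 10 of 48 and the elongation factors 3 of 6. Of the chemoreceptors 5 of 1314 had one (0.381%), of the F-box and MATH-BTB families 4 of 395, and of the lectins and lysozymes 6 of 256. Against shifted peaks 8 of the lists lay above and 2 below, while the elongation factors (permutation adjusted p = 0.104), the splicing factors (0.102) and the lectins and lysozymes (0.264) did not pass. With each replicate alone several counts moved: the ribosomal protein genes had 40 of 80 without replicate 1 and 10 of 80 without replicate 2, and oxidative phosphorylation had 24 of 53 without replicate 1. The tubulins and actins no longer passed without replicate 1 (4 of 21, exact adjusted p = 0.118), nor the splicing factors without replicate 2 (6 of 48, 0.087). The chemoreceptors had 8 of 1314 without replicate 1, still below the other genes. The moulting list passed without replicate 2 (6 of 32, exact adjusted p = 0.0164), and the detoxification list lay below without replicate 1 (2 of 185, exact adjusted p = 0.000742).

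All 6 occupied histone genes (hil-3, his-24, his-35, his-37, his-41 and his-72) were among the 17 with a unique promoter (35.3%), and 0 of the 63 with repeated promoter sequence were occupied, which allows up to 4.76% (Fisher's exact p = 4.1e-05). Over all other protein-coding genes the shares were 6.70% of 17526 with a unique promoter and 1.39% of 2367 with repeated sequence, a rate at which 0.878 of the 63 would be occupied. The genes for SL2 RNAs had a peak within 500 bp in 13 of 18 cases, and the repeated share of the promoter ran from 0.927 to 26.5% in the 5 without one and from 0 to 11.1% in the 13 with one. Among the SL1 RNA genes 0 of 12 had a peak, and all 12 promoters hold repeated sequence, at least 69.7% of each, so these lists leave the SL1 genes open.

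Peaks by heat shock genes were among those that ranked furthest apart between the replicates: the peak 141 bp past the 3′ end of hsp-90 ranked 23 in replicate 1 and 14468 in replicate 2, that 212 bp past hsp-16.48 ranked 14 and 3047, that past hsp-110 ranked 16 and 2215, and that 95 bp past hsp-16.2 ranked 129 and 22451. As a whole the heat shock list did not pass in the rank difference between replicates, measured among the 2806 optimal peaks found in both. The median was -290 over 35 peaks, 13 of them higher in replicate 2 (permutation adjusted p = 0.648 against lists matched on signal). With GC content added to the matching the permutation adjusted p was 0.496. With gene ends added it was 0.375 (0.0402 before adjustment). This test took only the strongest peak of each gene, so the peak 95 bp past hsp-16.2 was not in it. The promoter share of the list was 35.8% with replicate 2 alone and 37.3% with replicate 1 alone.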
